A study of Anser cygnoides with 9 samples.

How the data were processed

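Livers of 9 Sichuan white geese (Anser cygnoides), slaughtered at day 70 after being raised together, were used, 3 each of high, middle and low weight. Per the labels' protocols, total RNA was taken from frozen liver and 1 µg of it went into a stranded mRNA library for Illumina sequencing. Per the submitters' processing notes, HISAT2 2.0.4 and StringTie 1.3.0 were used. The counting tool, its strand setting and the genome build are not given in the sources used here, and coordinates are those of the scaffolds named in the files.

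The deposited files give, per the file headers, a raw read count and an FPKM value for each gene and library, with NCBI gene identifiers, names and descriptions. The counts are whole numbers that sum to between 10127778 and 15002506 per library. The deposited FPKM values of a gene equal its count divided by the library total and a length that is constant over libraries to within 0.0333%. A gene without a count is not listed in a library's file and was set to 0. Of 15711 genes, 11920 were counted in all 9 libraries, and 4572 carried a placeholder name. Gene names came from the files, and 13835 identifiers were also found in a RefSeq symbol table of a Taihu goose assembly, which was used for names and chromosome membership only, never for coordinates. It named 830 of the placeholders.

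The tests were designed before the data were examined and assumed FPKM values, with edgeR as the test if counts were found. As counts were found, genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, robust dispersions, and the quasi-likelihood F test on all 9 libraries with group as the only term and 6 residual degrees of freedom. The filter left 11756 genes, and the 3955 others held 0.0628% of all counts. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The biological coefficient of variation was 0.347 and the median standard error of a log2 difference was 0.32 in each pair of groups. Both come from the fit to all 9 libraries and set the precision of these tests. FPKM is given as mean ± SD over libraries, and fold changes come from the fit.

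Gene lists were also fixed before the data were examined. Of 43 lists, 38 had at least 5 tested members and were tested with camera from limma 3.58.1 at a preset correlation of 0.01. No list was called at the same threshold with the correlation estimated from the data or with fry, for its directional or its mixed p. List members were matched by file name or by symbol table name. The deviation of a list in a library is the median over members of log2 CPM (prior count 2) minus each gene's median over the 9 libraries. For the Z chromosome list, log2(FPKM + 1) was used in the group test, an exact permutation test over 20 arrangements.

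Genes named in the text followed a rule fixed before the data were examined. Genes past the threshold came first. As fewer than 10 passed in any comparison, 10 per direction were taken by lowest unadjusted p among genes with a symbol, no overlap between the 3 FPKM values of the groups and a larger group mean of at least 5 FPKM. These are values that did not pass. Of the genes this rule and the list rule select, 2 are not reported. In each called list at least 1 of the 4 members with the lowest p was named, and IGF1, GHR, FASN, SCD, PCK1, CYP7A1 and ALB were always given.

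Libraries were compared before averaging. Among genes with at least 20 counts in a pair, the chi-square per degree of freedom was at least 31.1 in all 36 pairs, so no library was a repeat of another. P-values of the gene tests measure the spread between birds of a group. Those of camera at the preset correlation of 0.01 largely treat the genes of a list as separate from one another. The correlations estimated for the called lists ran from 0.170 to 0.773, so these p-values do not measure the spread between birds. Each test was checked on simulated counts with the real means, spread and library sizes, in which 200 well counted genes were changed 2-fold or 4-fold. A list of 20 genes all raised 2-fold was called by camera in each of the 3 comparisons, also with an estimated correlation. The simulated genes were drawn independently, whereas the estimated correlation within that list was between 0.656 and 0.677 in the data, so this does not give the power for the real lists.

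The alternatives tried were other pseudocounts, filters, scalings and variance models, DESeq2 1.42.0, limma on log2(FPKM + 1), the replicate number as a block, the 6 libraries of a pair alone, and each library left out in turn. TPM and values per transcript were not used here. Genes that overlap or adjoin may share reads, since the strand setting of the counting is not given.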

Results

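Liver RNA from 9 Sichuan white geese was profiled at day 70 by stranded mRNA sequencing. The birds had been classed by body weight, and 3 livers each came from high, middle and low weight geese. Each liver is a separate library with its own replicate number, and no body weight or sex of a single bird is given in the labels. Total counts per library ran from 10127778 in middle weight replicate 1 to 15002506 in high weight replicate 2, and between 13321 and 14184 genes had at least 1 count in a library. The 3 middle weight libraries held the fewest counts, at most 10752747, and the smallest other library held 11760431 (low weight replicate 2). Depth thus runs with the middle weight group, and its effect beyond scaling was not tested. Of 15711 genes counted in any liver, 11756 had enough counts to be tested.

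The livers resembled one another closely, with 1 exception. Albumin alone, the main plasma protein made by hepatocytes, took between 8.71% and 13.3% of the counts in 8 libraries and 3.51% in middle weight replicate 3. The 13 mRNAs of the mitochondrial genome took 40.9% of the counts in that library and between 8.18% and 21.4% in the other 8. Across genes, Pearson's correlation of log2(FPKM + 1) with any other library lay between 0.900 and 0.935 for middle weight replicate 3. Among the other 8 libraries it lay between 0.967 and 0.982 within a group and between 0.963 and 0.979 across groups. The first principal component, with 37.9% of the variance, placed this library at -89.1 and the rest between -15.4 and 34.1.

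**Figure D1:**
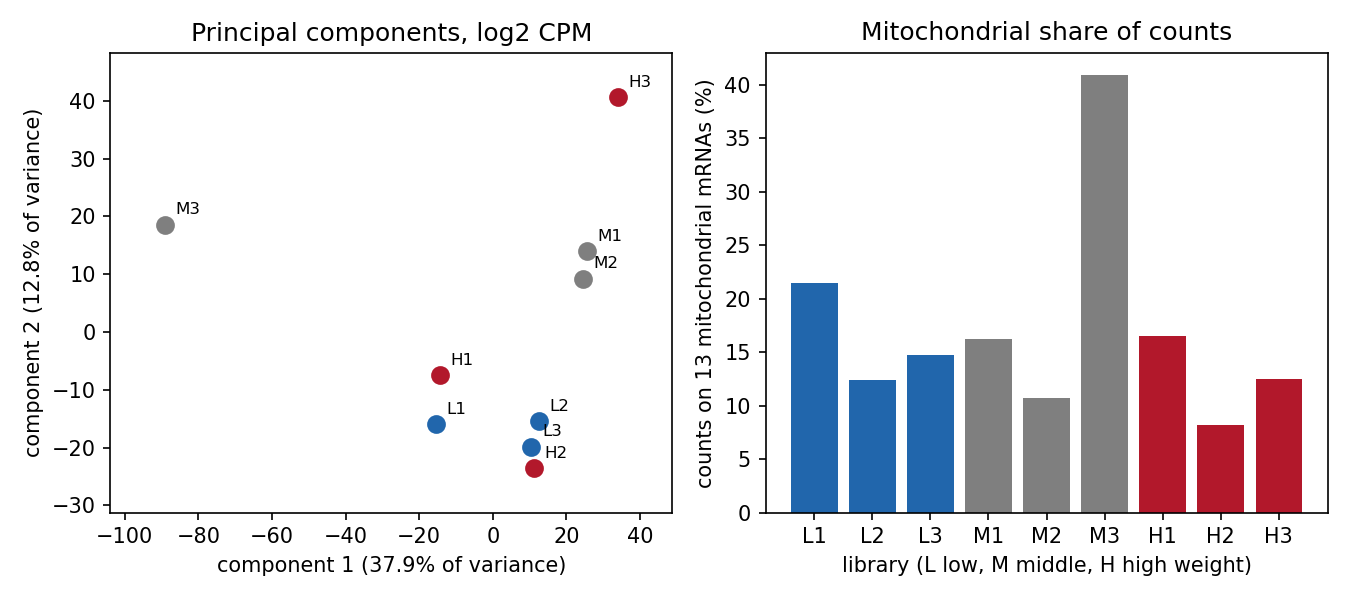
Left, the first 2 principal components of log2 CPM over the genes tested, 1 point per library; right, the percentage of all counts that fell on the 13 mitochondrial mRNAs. Middle weight replicate 3 (M3) lies apart at -89.1 on component 1 and holds 40.9% mitochondrial counts.

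Hepatocyte markers were lower in the same library. The median of 17 hepatocyte markers, taken as log2 deviation from each gene's median over the 9 livers, was -2.07 in middle weight replicate 3 and between -0.55 and 0.23 elsewhere. Markers of other liver cells were higher there, with a median of 1.39 for Kupffer cells and macrophages, 1.14 for cholangiocytes, 0.95 for B and plasma cells and 0.84 for stellate cells and fibroblasts. The median was 0.81 for T and NK cells and 0.59 for endothelium. Not all of these values were particular to this library. T and NK markers stood higher in low weight replicate 1, at 0.88. The highest other library had 1.13 for Kupffer cells and macrophages (high weight replicate 2) and 0.76 for stellate cells and fibroblasts (high weight replicate 1). It had 0.48 for endothelium and for B and plasma cells (low weight replicate 1), and 0.40 for cholangiocytes (low weight replicate 2). Because middle weight holds 3 livers, this library enters every comparison with that group. The fit was made on all 9 libraries, so it also enters the spread used for high against low weight. Over 812 genes at a mean of at least 50 FPKM, the median SD within groups was 0.396 on the log2 scale with this library and 0.308 without it.

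The first comparison set the ends of the weight range against each other, high against low weight. JAK2, the kinase that relays growth hormone signals, stood at 11.1 ± 0.478 FPKM in high weight livers and 6.46 ± 1.42 FPKM in low weight livers (SD, n = 3 each). ERRFI1, a feedback inhibitor of the EGF receptor, stood at 21.1 ± 12.4 against 5.13 ± 1.64 FPKM, and the immediate early gene FOS at 6.57 ± 3.32 against 1.92 ± 0.674 FPKM. RPS6KL1, a kinase-like gene, showed the reverse, with 6.79 ± 1.32 FPKM in high and 13.6 ± 2.31 FPKM in low weight livers. None of these differences passed the test over all genes.

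With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 11756 genes differed between high and low weight, and the smallest adjusted p was 0.99987. At an unadjusted p under 0.05 there were 277 genes, 73 higher and 204 lower in high weight, where 588 would arise by chance. Leaving out 1 library gave between 217 and 564 such genes, the most without middle weight replicate 3. DESeq2 and limma also called 0 genes. The high and low values did not overlap for 1001 genes, or 8.51% of those tested, and chance gives 10%. On simulated counts with the same spread, edgeR recovered 86 of 100 genes changed 4-fold in this comparison and 15 of 100 changed 2-fold. It also called 10 unchanged genes. The changed genes had an expected count above 100 before the change, and genes were drawn independently of one another. The genes of both sizes were changed in the same run, which makes the adjusted threshold easier to pass. In the real data fewer genes than by chance had an unadjusted p under 0.05 (277 against 588). These recoveries may therefore overstate the power of the real test. Real changes of that size need not be recovered, as ERRFI1, with a log2 difference of 1.97 (SE 0.46), was not called.

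Among the genes with the lowest unadjusted p and no overlap, the log2 difference was 0.79 (SE 0.18) for JAK2, 1.97 (SE 0.46) for ERRFI1 and 1.74 (SE 0.51) for FOS. CBR4, a carbonyl reductase of mitochondrial fatty acid synthesis, had 19.7 ± 1.56 against 11.8 ± 1.11 FPKM. The palmitoyltransferase gene ZDHHC20 had 7.86 ± 0.557 against 4.51 ± 0.346 FPKM, and the splicing factor gene SNRPG 26.1 ± 4.27 against 16.7 ± 0.435 FPKM. TLDC1, RASSF3 and SDCCAG3 were also higher in all high weight livers, by 0.99, 0.81 and 0.60 on the log2 scale.

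On the lower side, RPS6KL1 (gene identifier 106038863, scaffold NW_013185725.1, from 2949285 to 2955081) had a log2 difference of -1.01 (SE 0.20) and the lowest unadjusted p of the comparison. RGS9BP, which anchors a regulator of G-protein signalling, had 6.76 ± 1.12 FPKM in high and 18.1 ± 4.73 FPKM in low weight livers. RPL22L1, a ribosomal protein gene, had 65.8 ± 9.84 against 119 ± 3.81 FPKM. RFC5, a subunit of the clamp loader, had 11.8 ± 1.16 against 19.9 ± 5.90 FPKM, MSH3, of mismatch repair, 2.88 ± 0.677 against 5.17 ± 0.776 FPKM and KIF4A, a kinesin, 3.01 ± 0.851 against 5.59 ± 1.31 FPKM. The remaining genes of this set were ZNF711 (-0.74), the autophagy gene ATG14 (-0.74), RABEPK (-0.65) and TMED3 (-0.98), as log2 differences.

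**Figure D2:**
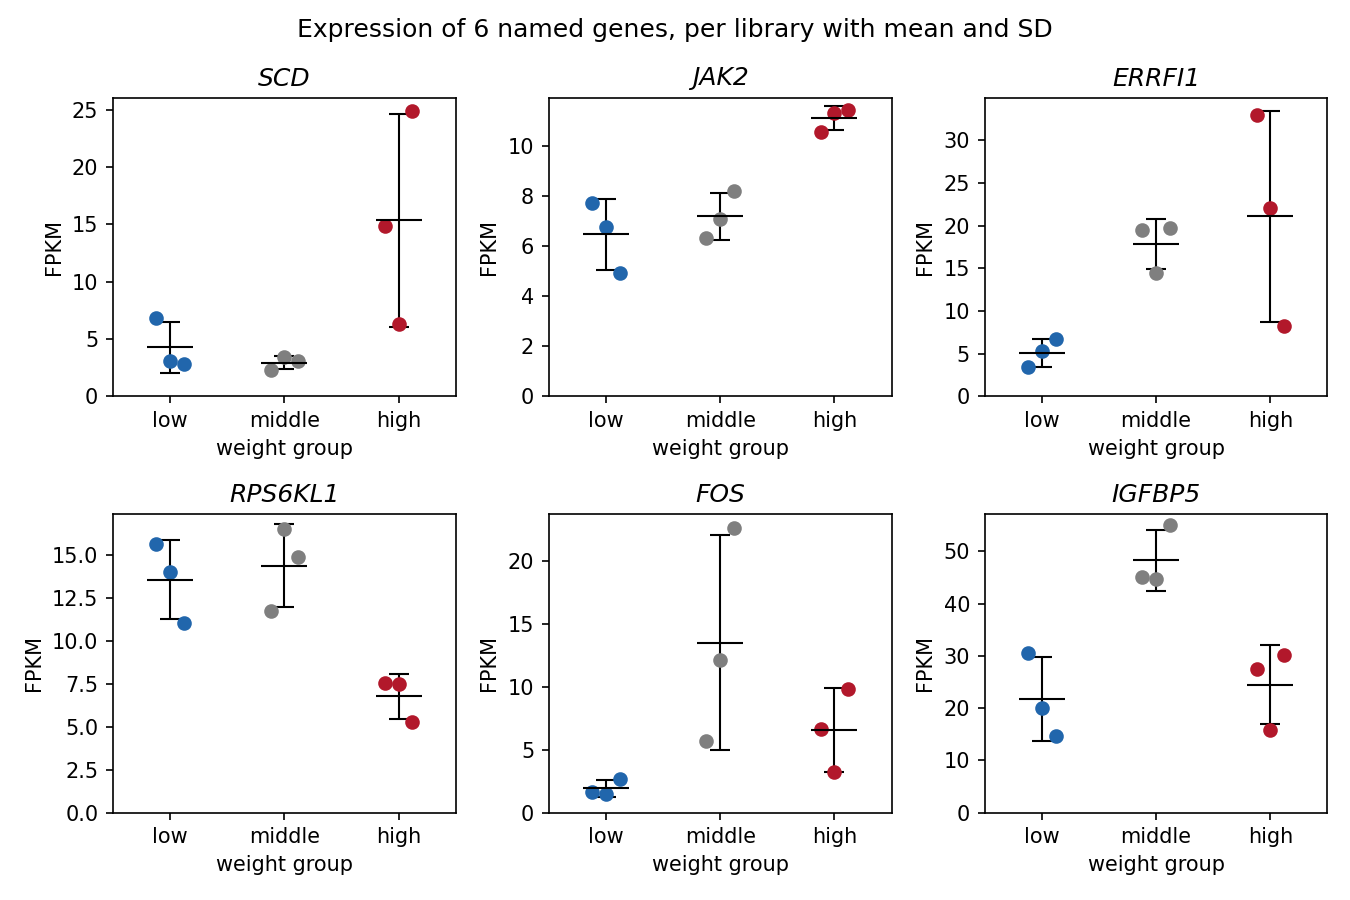
FPKM of 6 named genes in each liver by weight group, with the group mean (bar) and SD (whiskers), n = 3 per group. JAK2 lies between 10.5 and 11.4 FPKM in the high weight livers and RPS6KL1 between 5.26 and 7.58 FPKM, and SCD in 1 high weight liver (6.32) lies below the highest low weight liver (6.81).

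Of 38 gene lists tested with camera, 5 were called between high and low weight, 4 higher and 1 lower in high weight livers. The list of fatty acid synthesis and desaturation rose, with 14 of 18 members higher and a median log2 difference of 0.15 (adjusted p = 9.936e-04). It was not called with the correlation estimated from the data (adjusted p = 0.967 with an estimated correlation). SCD, the stearoyl-CoA desaturase, had 15.3 ± 9.29 FPKM in high and 4.26 ± 2.21 FPKM in low weight livers, ELOVL6, which lengthens palmitate, 86.0 ± 16.9 against 46.0 ± 9.13 FPKM, and ACACA, the acetyl-CoA carboxylase, 38.2 ± 7.17 against 21.0 ± 1.88 FPKM. No member passed over all genes or adjusted over the list alone (0 and 0 of 18).

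The heat shock list rose, with 17 of 20 members higher and a median of 0.29 (adjusted p = 1.783e-04, and adjusted p = 0.967 with an estimated correlation). HSPA2 had 159 ± 104 FPKM in high and 43.1 ± 12.03 FPKM in low weight livers, and HSP90AA1 392 ± 254 against 177 ± 25.1 FPKM. High weight replicate 3 carried much of this, with HSP90AA1 at 686 FPKM (533 FPKM in middle weight replicate 3), and without it the list's adjusted p was 0.121. Stellate cell and fibroblast markers rose in 12 of 15 members (median 0.58, adjusted p = 2.688e-04, and adjusted p = 0.967 with an estimated correlation), and the extracellular matrix list in 23 of 34 (median 0.09, adjusted p = 0.0162, and adjusted p = 0.967 with an estimated correlation). LUM, a collagen-binding proteoglycan, had 5.16 ± 6.44 against 0.968 ± 0.780 FPKM and LOX, which cross-links collagen, 5.14 ± 0.640 against 3.12 ± 0.344 FPKM. MMP9, a matrix protease with the lowest unadjusted p in the matrix list, went the other way, at 0.347 ± 0.0562 against 0.833 ± 0.352 FPKM. These last 2 lists were lost without high weight replicate 1 (adjusted p = 0.122 and 0.943), and without low weight replicate 1 the markers had an adjusted p of 0.172 and the matrix list turned lower (0.981). The matrix list was also lost among genes at a mean of at least 5 FPKM. In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone.

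The list of Z chromosome genes was lower in high weight livers, with 42 of 58 members negative and a median of -0.20 (adjusted p = 9.936e-04, and adjusted p = 0.967 with an estimated correlation). REEP5, of the ER membrane, had 10.6 ± 1.90 against 14.1 ± 1.83 FPKM and DCP2, an mRNA decapping enzyme, 1.79 ± 0.705 against 2.60 ± 0.280 FPKM, and 0 of the 58 members passed over all genes or adjusted over the list alone. In birds females carry 1 Z and males 2, and Z genes are only partly compensated. The shift did not run through the group: on the scale of log2(FPKM + 1), the median deviation of the list was 0.09 in high weight replicate 1, -0.15 in replicate 2 and -0.23 in replicate 3. The 3 low weight livers had 0.07, 0.11 and 0.00, and the middle weight livers -0.06, 0.00 and -0.13. On log2 CPM after TMM scaling, the scale of the other lists, the median was -0.53 in middle weight replicate 3, -0.18 and -0.15 in high weight replicates 2 and 3, and 0 or higher in the other 6. An exact permutation test, two-sided, on these library values gave p = 0.3 for high against low weight, where 20 arrangements allow no p below 0.1. The same exact permutation test gave p = 0.8 for high against middle weight and p = 0.2 for middle against low weight.

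**Figure D3:**
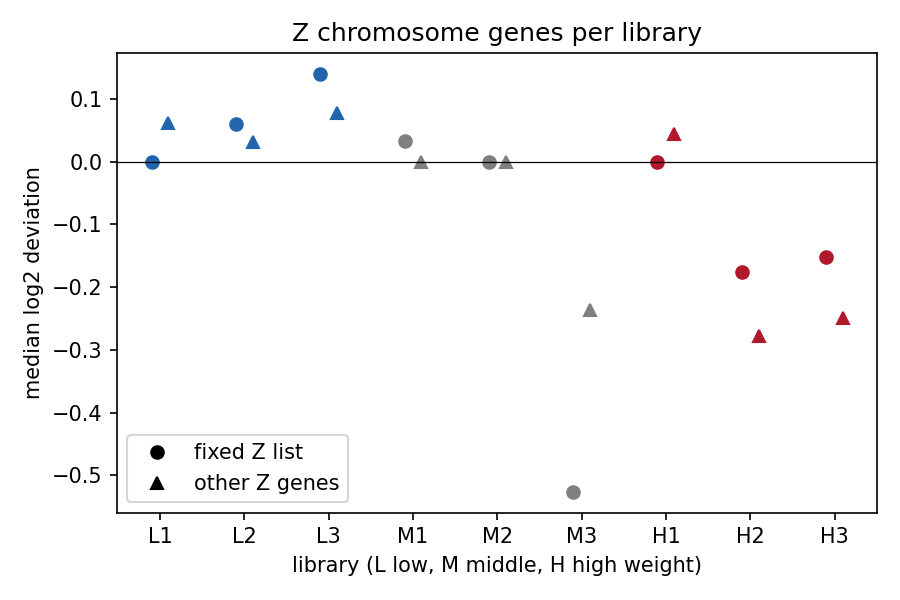
Median log2 deviation from the 9-library median of the fixed Z list (circles, 58 genes) and of the other Z genes (triangles, 503 genes) in each library, after TMM scaling. High weight replicates 2 and 3 and middle weight replicate 3 lie lowest in both sets.

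High weight livers were next compared with middle weight livers. SCD again stood out, at 15.3 ± 9.29 FPKM in high and 2.94 ± 0.564 FPKM in middle weight livers (SD, n = 3 each), a log2 difference of 2.45 (SE 0.50). ABHD5, an activator of triglyceride hydrolysis, had 15.7 ± 5.35 against 9.22 ± 1.43 FPKM, GLDC of the glycine cleavage system 31.5 ± 13.9 against 16.8 ± 1.19 FPKM, and SUCLA2 of the citrate cycle 19.6 ± 2.64 against 13.1 ± 1.67 FPKM. Lower in high weight were RPS6KL1, at 6.79 ± 1.32 against 14.4 ± 2.43 FPKM, and ANKZF1, of the ribosome quality control pathway, at 16.5 ± 5.06 against 31.7 ± 6.002 FPKM. None of these passed the test over all genes.

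In edgeR's quasi-likelihood test 0 of 11756 genes differed between high and middle weight after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.960. At an unadjusted p under 0.05 there were 412 genes, 126 higher and 286 lower, against 588 by chance. With 1 library left out there were between 318 and 674, with 674 without middle weight replicate 1 and 632 without replicate 2. DESeq2 called 3 genes, SCD (adjusted p = 0.0223), RPS6KL1 (0.0434) and PTK7 (0.0434), and limma called 0. The values did not overlap for 910 genes, or 7.74%, where chance gives 10%. On simulated counts edgeR recovered 81 of 100 genes changed 4-fold in this comparison and 9 of 100 changed 2-fold. As for high against low weight, this may overstate the power of the real test.

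The other genes higher in all 3 high weight livers with the lowest unadjusted p were JAK2 (0.69), FAM204A (0.69), ZDHHC20 (0.88), TTC13 (0.73), GNPNAT1 (0.90) and TOMM20 (0.58), given as log2 differences. GNPNAT1, which makes N-acetylglucosamine phosphate, had 61.2 ± 18.6 against 34.1 ± 3.60 FPKM, and TOMM20 of the mitochondrial import pore 22.2 ± 1.33 against 15.3 ± 2.06 FPKM. The lower set held PRUNE (-0.57), ZNF711 (-0.75), KANSL2 (-0.73), PTK7 (-0.59), HOGA1 (-0.95), UCKL1 (-0.58) and PLBD2 (-0.60). PPAPDC2, a lipid phosphatase, had 12.6 ± 1.81 FPKM in high and 34.1 ± 27.1 FPKM in middle weight livers, with 65.3 FPKM in middle weight replicate 3.

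Camera called 8 of 38 lists between high and middle weight, 6 higher and 2 lower in high weight. The fatty acid synthesis list rose in 15 of 18 members (median 0.41, adjusted p = 2.557e-05, and adjusted p = 0.912 with an estimated correlation), and SCD passed when adjusted over the list alone (1 of 18). FASN, the fatty acid synthase, had 82.0 ± 55.9 against 29.3 ± 9.31 FPKM, and ACACA 38.2 ± 7.17 against 19.7 ± 7.86 FPKM. The cholesterol synthesis list rose in 19 of 20 members (median 0.55, adjusted p = 4.986e-08, and adjusted p = 0.912 with an estimated correlation). IDI1 of the isoprenoid pathway had 115 ± 48.2 against 52.0 ± 23.1 FPKM. In middle weight replicate 3 the median deviation was -0.87 for fatty acid synthesis and -1.77 for cholesterol synthesis. Without that library the adjusted p rose to 0.04947 for fatty acid synthesis and 0.0257 for cholesterol synthesis, and cell cycle stood at 0.0151.

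Triglyceride synthesis and lipid droplet genes rose in 13 of 19 members (median 0.20, adjusted p = 0.00493), ER stress and chaperone genes in 22 of 25 (median 0.46, adjusted p = 7.924e-05), amino acid catabolism genes in 27 of 38 (median 0.17, adjusted p = 0.00771) and hepatocyte markers in 16 of 17 (median 0.30, adjusted p = 0.0128). None of these 4 was called with a correlation taken from the data (adjusted p = 0.912 with an estimated correlation). AGPAT2, of triglyceride synthesis, had 61.4 ± 6.45 against 38.4 ± 7.14 FPKM, MANF, an ER stress protein, 39.9 ± 9.46 against 30.8 ± 8.32 FPKM and MAT1A, which makes S-adenosylmethionine, 203 ± 99.4 against 115 ± 11.7 FPKM. The hepatocyte transcription factor gene HNF4A had 13.01 ± 8.49 against 8.72 ± 0.880 FPKM. Cell cycle genes fell in 44 of 48 members (median -0.27, adjusted p = 5.000e-05) and endothelial markers in 18 of 19 (median -0.34, adjusted p = 0.00236). These calls were lost too (adjusted p = 0.912 with an estimated correlation). PBK, a mitotic kinase, had 0.605 ± 0.224 against 1.51 ± 0.409 FPKM, and EGFL7 of endothelium 12.97 ± 1.35 against 25.5 ± 17.8 FPKM. In these 6 lists 0 members passed over all genes or adjusted over the list alone.

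Middle weight replicate 3 decided part of this. Without it the amino acid catabolism list turned lower in high weight (adjusted p = 0.02401), hepatocyte markers turned lower (0.0535), and the triglyceride (0.492), ER stress (0.06782) and endothelial (0.380) lists were no longer called. The triglyceride and amino acid lists were also lost in limma with quantile normalization, and the cell cycle list held fewer than 5 genes at a mean of at least 5 FPKM, so it was not tested there. The count without it was 18 lists, of which 4 were among the 8. High weight replicate 3 also mattered: without it amino acid catabolism (0.110), cell cycle (0.05857) and hepatocyte markers (0.131) were lost.

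**Figure D4:**
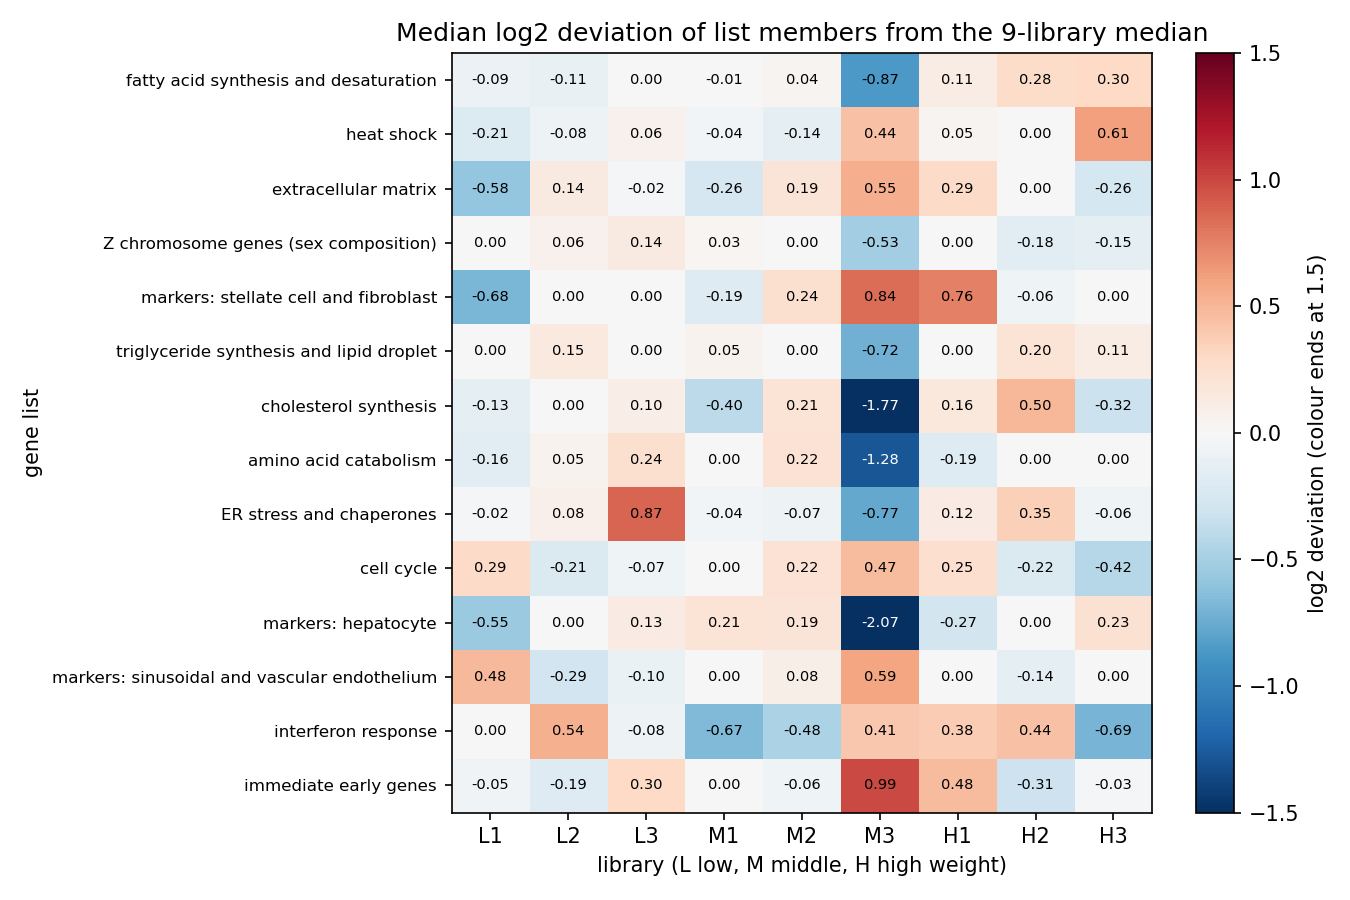
Median log2 deviation from the 9-library median over the members of each gene list called in at least 1 comparison, per library after TMM scaling; red is higher and blue lower. Middle weight replicate 3 (M3) shows -2.07 for hepatocyte markers and -1.77 for cholesterol synthesis, and low weight replicate 3 (L3) 0.87 for ER stress.

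The third comparison was middle against low weight. FOS had 13.5 ± 8.56 FPKM in middle and 1.92 ± 0.674 FPKM in low weight livers (SD, n = 3 each), a log2 difference of 2.62 (SE 0.52). RGS5, a marker of pericytes, had 28.2 ± 20.6 against 7.03 ± 3.02 FPKM, IGFBP5, a secreted binding protein for insulin-like growth factors, 48.3 ± 5.86 against 21.8 ± 8.003 FPKM and ERRFI1 17.9 ± 2.94 against 5.13 ± 1.64 FPKM. Lower in middle weight were RGS9BP, at 6.34 ± 2.01 against 18.1 ± 4.73 FPKM, and IRS2, an adaptor of the insulin receptor, at 4.20 ± 0.706 against 8.31 ± 3.27 FPKM. None of these passed the test over all genes.

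Again 0 of 11756 genes differed after Benjamini-Hochberg adjustment in edgeR's quasi-likelihood test, with a smallest adjusted p of 0.99978. At an unadjusted p under 0.05 there were 332 genes, 213 higher and 119 lower in middle weight, against 588 by chance. This number lay between 226 and 613 with 1 library left out, at 613 without middle weight replicate 3 and 575 without replicate 2. DESeq2 called 4 genes, FOS (adjusted p = 0.00864), KCTD21 (0.00864), PLEKHS1 (0.00922) and KCNE4 (0.0261), of which the last 3 were named after their values were seen, and limma called 0. Those 3 were low, with at most 2.90 FPKM in any liver. PLEKHS1 had 1.87 FPKM in middle weight replicate 3 and 0.48 and 0.40 FPKM in replicates 1 and 2. FOS (22.7 FPKM) and KCNE4 (2.90 FPKM) were also highest in middle weight replicate 3. The values did not overlap for 779 genes, or 6.63%, where chance gives 10%. On simulated counts edgeR recovered 79 of 100 genes changed 4-fold in this comparison and 7 of 100 changed 2-fold. Here too this may overstate the power of the real test.

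Of the genes higher in all 3 middle weight livers, the others with the lowest unadjusted p were EPHB1 (0.86), NTMT1 (0.70), DPM2 (0.66), USP36 (0.70), CCDC12 (0.65) and DCPS (0.60), as log2 differences. Among those lower in all 3, the others with the lowest unadjusted p were AKAP11 (-1.54), CRELD2 (-1.57), CMTR1 (-1.09), RBX1 (-0.91), CMPK1 (-0.75), FAM204A (-0.58), BFAR (-0.54) and LNPEP (-0.80). RBX1, a subunit of cullin ubiquitin ligases, had 5.45 ± 0.300 against 9.93 ± 0.0501 FPKM, and the ER protein gene CRELD2 18.7 ± 2.95 against 53.2 ± 30.6 FPKM.

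Camera called 11 of 38 lists between middle and low weight, 5 higher and 6 lower in middle weight. ER stress and chaperone genes fell in 22 of 25 members (median -0.69, adjusted p = 5.458e-10, and adjusted p = 0.927 with an estimated correlation). HSP90B1, the ER chaperone GRP94, had 180 ± 42.2 FPKM in middle and 484 ± 385 FPKM in low weight livers, and PDIA6 61.6 ± 8.26 against 122 ± 52.7 FPKM. Low weight replicate 3 stood highest for this list, with a median deviation of 0.87 and HSPA5 at 705 FPKM, where the other 8 livers lay between 122.6 and 305 FPKM. Cholesterol synthesis fell in 18 of 20 members (median -0.47, adjusted p = 1.686e-05), amino acid catabolism in 32 of 38 (median -0.27, adjusted p = 6.952e-05), the interferon response in 15 of 19 (median -0.32, adjusted p = 0.00113), the Z chromosome list in 47 of 58 (median -0.16, adjusted p = 2.839e-04) and hepatocyte markers in 14 of 17 (median -0.10, adjusted p = 0.0495). These 5 lists had an adjusted p = 0.927 with an estimated correlation. CMPK2, an interferon-induced kinase, had 8.92 ± 4.91 against 29.9 ± 20.1 FPKM, and UROC1 of histidine breakdown 16.7 ± 5.92 against 33.3 ± 2.94 FPKM. MSMO1 of sterol synthesis had 43.8 ± 38.2 against 86.2 ± 15.01 FPKM, REEP5 on the Z chromosome 10.6 ± 1.33 against 14.1 ± 1.83 FPKM and HNF4A 8.72 ± 0.880 against 13.2 ± 4.11 FPKM.

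The lists that rose were stellate cell and fibroblast markers in 13 of 15 members (median 0.37, adjusted p = 2.839e-04), extracellular matrix in 28 of 34 (median 0.29, adjusted p = 3.703e-04), cell cycle in 37 of 48 (median 0.19, adjusted p = 3.703e-04), endothelial markers in 15 of 19 (median 0.18, adjusted p = 0.0102) and immediate early genes in 17 of 22 (median 0.35, adjusted p = 0.0207). All 5 had an adjusted p = 0.927 with an estimated correlation. Adjusted over the list alone, FOS passed among the immediate early genes (1 of 22) and RGS5 among the stellate markers (1 of 15), and 0 members of the other 9 lists passed. RGS5 had 51.7 FPKM in middle weight replicate 3 and 19.3 and 13.5 FPKM in replicates 1 and 2. The highest low weight liver had 10.2 FPKM. JUN had 27.5 ± 25.3 against 11.9 ± 4.003 FPKM, COL1A1 9.59 ± 6.51 against 4.56 ± 0.762 FPKM, the mitotic gene CDC20 1.76 ± 0.341 against 0.896 ± 0.281 FPKM and VWF of endothelium 3.06 ± 1.33 against 1.60 ± 0.0591 FPKM.

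Without middle weight replicate 3, 3 of the 11 lists were called in either direction: ER stress, interferon response and hepatocyte markers, the last now higher in middle weight (adjusted p = 0.006421). The median deviations in that library were -1.28 for amino acid catabolism, 0.99 for immediate early genes, 0.84 for stellate markers and 0.55 for extracellular matrix. Other livers decided lists as well. The interferon list was lost without middle weight replicate 1 (0.187), middle weight replicate 2 (0.1945) or low weight replicate 2 (0.115), and hepatocyte markers without low weight replicate 2 (0.199), low weight replicate 3 (0.3904) or high weight replicate 3 (0.05575). Without low weight replicate 1 extracellular matrix (0.3955), stellate markers (0.168) and immediate early genes (0.168) were lost. Without low weight replicate 2 immediate early genes (0.282), cell cycle (0.126) and endothelial markers (0.445) were lost, and endothelial markers also without low weight replicate 3 (0.3904). In limma on log2 FPKM with a pseudocount of 0.1, 0.5 or 1 immediate early genes were not called, nor were endothelial markers among genes at a mean of at least 5 FPKM, where the cell cycle list held fewer than 5 genes and was not tested.

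A test for any difference among the 3 groups called 0 of 11756 genes in edgeR's quasi-likelihood fit with Benjamini-Hochberg adjustment (smallest adjusted p 0.99992), and 305 had an unadjusted p under 0.05 (590 without middle weight replicate 3). DESeq2 called 10, among them SCD (adjusted p = 0.0212), JAK2 (0.0269), RPS6KL1 (0.0269) and FOS (0.0295), and limma called 0. A linear trend over low, middle and high weight called 0 of 11501 genes, with 255 at an unadjusted p under 0.05 (528 without middle weight replicate 3), and DESeq2 and limma also called 0. On simulated counts edgeR recovered 86 of 100 genes changed 4-fold in 1 group in the first of these tests and 35 of 100 in the second. A change in 1 group is not a linear trend. The 35 of 100 therefore does not give the recovery of a change that follows weight order. For the test of any difference, the 86 of 100 may overstate the power on the real data, as in the pairs.

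Of the 7 genes followed in every group, IGF1, the growth factor made by the liver under growth hormone, had 5.10 ± 2.14 FPKM in high, 6.97 ± 3.59 in middle and 7.56 ± 2.51 in low weight livers. The growth hormone receptor gene GHR had 183 ± 47.3, 137 ± 62.0 and 179 ± 38.5 FPKM in the same order. PCK1, of gluconeogenesis, had 335 ± 505, 163 ± 198 and 102 ± 66.0 FPKM. ALB had 64770 ± 8489, 51468 ± 28346 and 55960 ± 8448 FPKM. LOC106039033, which the symbol table names CYP7A1, the rate-limiting enzyme of bile acid synthesis, had 0.713 ± 0.488, 1.99 ± 1.34 and 0.478 ± 0.352 FPKM. FASN had 41.4 ± 21.5 FPKM in low weight livers, beside the values above, and high weight replicate 1 held the highest value, at 146 FPKM.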

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

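The 3 pairwise tests, the test of any difference and the trend each called 0 genes under median-ratio scaling, no filter, a mean of at least 5 FPKM, limma with pseudocounts of 0.1 and 0.5, quantile normalization, sample weights, no trend or robust step, and, for the pairs, the 6 libraries alone. Leaving out the mitochondrial mRNAs, limma on log2(FPKM + 1) and limma voom with quality weights were chosen after the data were seen and also called 0. DESeq2 called 3 genes in high versus middle, 4 in middle versus low and 10 in the test of any difference, and without a filter 1, 3 and 1; the cause was not tested. Leaving out 1 library gave 0 to 1 genes in high versus low, high versus middle and any difference, the 1 being SLC25A51 without high weight replicate 3. With the replicate number as a block the 5 counts stayed at 0, and the lists called were 6, 8 and 12. The labels do not say that the numbers pair the birds. In a check, 2 of 9 same-number pairs had a correlation of deviations above 0.1, and 1 of 9 libraries correlated best with its own number. Middle weight replicate 3 weighs on the group mean behind these deviations, so the check cannot exclude a batch shared by number. The lists called were 5, 8 and 11 in high versus low, high versus middle and middle versus low. Lists were gained as well, among them ER stress and chaperones in high versus low at a mean of at least 5 FPKM, in limma with each pseudocount and with quantile normalization, and heat shock in middle versus low under the same settings and with the block; the cause was not tested. With an estimated correlation and with fry they were 0, 0 and 0. Leaving out 1 library gave 5 to 10, 6 to 18 and 7 to 19 lists; fewer samples enter, and otherwise the cause was not tested. Lists turned direction in 6 cases: extracellular matrix in high versus low without low weight replicate 1 (adjusted p = 0.981), and without middle weight replicate 3 amino acid catabolism (0.02401) and hepatocyte markers (0.0535) in high versus middle, and amino acid catabolism (0.356), immediate early genes (0.441) and hepatocyte markers (0.006421) in middle versus low. Over the libraries left out that kept their direction, the adjusted p of these lists ran from 1.801e-05 to 0.943 for extracellular matrix in high versus low. In high versus middle it ran from 3.804e-06 to 0.1104 for amino acid catabolism and from 1.302e-04 to 0.1305 for hepatocyte markers. In middle versus low it ran from 4.616e-09 to 0.02214 for amino acid catabolism, from 1.301e-04 to 0.282 for immediate early genes and from 3.553e-04 to 0.3904 for hepatocyte markers. At a mean of at least 5 FPKM the cell cycle list held fewer than 5 genes and has no value. Of 478 alternative values of the called lists, 388 kept call and direction and 84 lost the call. The 60 named gene results kept their direction in all 1492 alternative values, 6 of them now past the threshold, all with DESeq2. These genes were chosen for groups without overlap and for a low p in the same libraries. Their direction could therefore hardly turn, and this count does not show that the differences are robust. The Z list difference between high and middle weight was -0.03, and 0.01314 with members above a mean of 5 FPKM, and the cause was not tested. TPM and values per transcript were not run. With 3 livers per group, most simulated 2-fold changes were not recovered by these tests.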

Other observations

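Some genes differed widely between single birds within a group. PCK1 had 917 FPKM in high weight replicate 2 and 25.2 FPKM in replicate 1, and 392 FPKM in middle weight replicate 1 and 44.4 FPKM in replicate 2. G6PC, the last step of glucose release, lay between 149.9 and 715 FPKM in high weight livers. CHAC1, which breaks down glutathione, lay between 14.5 and 341 FPKM in high weight and between 12.2 and 181 FPKM in low weight livers. GATM of creatine synthesis lay between 11.9 and 250.3 FPKM in high weight livers, and SAA2, an acute phase gene, between 159.5 and 1359 FPKM in low weight livers. PCK1 is always given, and the others were named after their values were seen, as genes with a wide spread within groups among the 812 at a mean of at least 50 FPKM.

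Kupffer cell and macrophage markers also varied within groups, with a median deviation of 1.13 in high weight replicate 2 and -1.61 in replicate 3. The interferon list had 0.44 and -0.69 in the same livers. SLC25A51, the mitochondrial carrier of NAD, had 0 counts in high weight replicates 1 and 2 and between 92 and 163 in the other 7 libraries. The gene before it on scaffold NW_013186071.1, LOC106049674, from 107520 to 118071, had 136 and 75 counts in those 2 libraries and 0 in the other 7. SLC25A51 starts at 118181. Summed over both genes the counts lay between 75 and 163. Among genes up to 3 places apart, this was the only pair with complementary zeros over the 9 libraries and at least 20 counts in 1 of the genes in every library. The 0 counts of SLC25A51 therefore do not show that it was silent in those livers, and its call without high weight replicate 3 does not show a change in expression.

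Of the tests from here on, those of gene length and of the fatty acid list minus the hepatocyte markers were set before the result was seen, and all others after it. Middle weight replicate 3 had a hepatocyte marker median of -2.07. Without the mitochondrial mRNAs the median was -2.02 (SE 0.21), and at least -0.54 in the other 8 libraries. The values were already scaled by TMM, so leaving these mRNAs out could hardly move the median and decides nothing. Mitochondrial mRNAs taking counts would lower all other genes alike. The 9 other marker lists ran from -0.26 to 1.39 in this library, which argues against that as the cause of the low hepatocyte markers. A net loss of long transcripts was not seen, as the slope of the deviations on log2 gene length was 0.0802, above the range of -0.0572 to 0.0153 in the others. The marker genes that shifted in this library also enter the slope, so it cannot exclude RNA degradation. A smaller share of hepatocytes should raise the other marker lists alike. Over 9 lists a permutation of members gave p = 0.00590, with 8 lists between 0.50 and 1.39 and the adipocyte list, of 6 tested genes, at -0.26. Without the adipocyte list the permutation p was 0.140, but that list was picked for its value. As fixed, the adipocyte list shares CEBPA with the hepatocyte markers and other genes with the triglyceride and lipoprotein lists. The permutation also treated members as independent. Neither p therefore decides whether a smaller share of hepatocytes was the only cause. A change of state of the hepatocytes themselves stays open, and beyond the cell makeup no biological explanation was tested.

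Z chromosome genes were lower in high weight replicates 2 and 3 and middle weight replicate 3. In 503 Z genes outside the list, the medians were -0.28, -0.25 and -0.24 in these libraries and 0 or higher in the other 6, a gap of 0.237. The lowest of 1000 random autosomal sets of that size was -0.00572, -0.0162 and -0.123. A candidate explanation is that these 3 birds were female and the other 6 male, a hypothesis from the values that the labels do not settle. Hepatocyte medians did not show a smaller share of hepatocytes in high weight replicates 2 and 3, at 0 and 0.23. Low weight replicate 1, at -0.55, had no low Z genes. The fixed list was at -0.18 and -0.15 in high weight replicates 2 and 3 and -0.53 in middle weight replicate 3. Hepatocyte medians of those 2 replicates lay at least 0.692 (SE 0.298) above what a fall in proportion would give. In middle weight replicate 3 the hepatocyte median was -1.52 (SE 0.226) from the lowest other library. There a smaller share cannot be told apart from sex, as both would act in that library. Both standard errors treat list members as independent. The correlation estimated in high versus low weight was 0.78 for hepatocyte markers and 0.25 for the Z list. The standard errors are therefore too small to decide.

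The fatty acid synthesis list was higher in high than in low weight livers, with medians of 0.11, 0.28 and 0.30 against -0.09, -0.11 and 0.00. A larger share of hepatocytes could contribute: the difference of the list median minus the hepatocyte median was 0.167, within its standard error of 0.214. Sex makeup could contribute as well, since high weight replicate 1, whose Z genes were at the level of the low weight livers, lay 0.109 above the highest of them, within the standard error over members of 0.252. Both cannot be told apart from a difference between weight groups with 3 livers each, which stays open.

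For the counts of genes, 10 splits of 6 libraries are too few for a share under 0.05. The real split called 0 genes in each pair, and the highest other split called 0 in high versus low, 12 in high versus middle and 1 in middle versus low. The 12 came from setting high weight replicates 1 and 2 with middle weight replicate 3 against the other 3, which points to some structure of the samples that was not tested against chance. Over 100 drawn splits of the 9 libraries, the real one included, 100 called at least the 0 genes of the real one, both for any difference (highest other 4) and for the trend (highest other 10). With 0 in the real split this holds for any split, so these counts decide nothing about chance.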
